A study of Paulownia elongata with 6 samples.

How the data were processed

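Per the labels' protocols, total RNA from leaves was made into barcoded libraries with Illumina's TruSeq RNA kit and read as paired 76-base reads on a MiSeq, a small benchtop sequencer. The plants were Paulownia elongata, a fast-growing tree, and the labels give an age of 3 years beside 14 days of growth in potting soil. The 6 libraries fall into 3 from plants held at 40 °C for 24 hours, with 12 hours of light and 12 of dark, and 3 from control plants at 25 °C. The labels do not say that the libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical.

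The authors quantified each library with Salmon, per the submitters' processing notes. The version, the transcript reference and its annotation are not given in the sources used here. Each deposited per-library file lists 43380 transcript models with Salmon's estimated counts (reads assigned to a model, not whole numbers because shared reads are divided), its TPM values (abundance scaled by effective length within a library) and its lengths, per the file headers. The identifiers carry a component, a gene, an isoform and a model number, and name 39038 genes by that scheme, 3772 of them with 2 or more models. Of the model lengths, 99.99% are multiples of 3, so they are coding lengths, from 156 to 6456 bases with a median of 369. The identifiers are not paired with gene names or descriptions in the files, and no genome or annotation was used here, so no chromosome position can be given. The 24 gene lists and 6 lists of markers for other cell types and organisms that were fixed before the data were examined could therefore not be tested, and none has a result.

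The authors also deposited a table of their own comparison, with a log2 fold change, a mean log2 CPM, a p-value and an FDR for each of 43380 models, per the file headers. edgeR is named in the submitters' processing notes, without a version given in the sources used here. An edgeR exact test on the rounded counts with plain library totals gave log2 fold changes that correlated with the deposited ones at r = -1.00 across 43376 models. After reversing the sign the differences had a median of 0.00051 and a maximum of 0.234. The deposited fold changes are therefore coded as control relative to heat, and they are printed here with the sign reversed.

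For the main comparison, the estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Models were kept by edgeR's expression filter (a count of at least 10 scaled to library size in 3 libraries, and a total of at least 15), which left 23984 models and removed 19396. Libraries were scaled by TMM. The robust quasi-likelihood test compared the groups in a model with group alone, and p-values were adjusted by the Benjamini-Hochberg method over all tested models, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values used the TMM-scaled library sizes, and log2 CPM used a prior count of 1. Ratios of pooled reads have exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only.

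Depth ran from 730315 to 3570524 estimated reads per library. A count of 0 allows a level of up to 3 counts, which was 0.91 CPM in the deepest library and 4.76 CPM in the shallowest. The fragment length that Salmon used was read from the deposited files as the median of length minus effective length over models longer than 1000 bases. Libraries above and below 150 bases were called long-fragment and short-fragment libraries, a division made after the data were seen. For checks of depth, counts were thinned at random to 730265 reads per library, 20 times.

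The rule for naming transcripts, fixed before the data were examined, took up to 2 called models that rose and up to 2 that fell, where the groups did not overlap and the higher group had a mean of at least 20 reads. It gave 1 model. A further 3 were chosen after their values were seen, as those with the smallest p-values in the authors' deposited table, 1 higher and 2 lower in heat. Alternatives were other scalings (DESeq2 size factors, library totals), no filter or a minimum total of 60 reads, DESeq2 1.42.0 with its own size factors and independent filtering, edgeR's exact test, limma-voom (limma 3.58.1), a replicate block, effective lengths as offsets, a test against a 1.5-fold change, isoforms summed to genes, and each library left out in turn. Alternatives added after the data were seen were fragment length as a covariate, controls 1 and 2 left out, a threshold of 0.10, DESeq2 on the filtered models with TMM scaling, and an exact test with library totals and no filter. That test matched the authors' fold changes but not all their calls, with 2264 higher and 1518 lower against 2196 and 1486, and 3647 of their 3682 calls shared. The comparisons that share no library were also run without each library in turn.

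The labels number the libraries 1 to 3 in both groups. Deviations from the group means correlated between same-numbered libraries at r = 0.01, 0.18 and 0.35. Between differently numbered libraries r ran from -0.31 to 0.28. Deviations within a group are tied to each other by its mean, so these values cannot settle a pairing. No label states one, and the numbers were not taken to pair the libraries. No pair of libraries in a group agreed within sampling noise. The chi-square per degree of freedom over models with at least 10 reads was lowest, at 6.05, between controls 1 and 2. The tests were checked on simulated counts drawn from the means, library sizes and spread of these libraries, with 200 changed models. The changed models were taken from those with a mean of at least 20 reads. With the spread of all 6 libraries, over 23984 models, the quasi-likelihood test recovered 62% of 16-fold changes and 0% of 4-fold changes, with 3 false calls. The exact test recovered 95% and 14%, with 31 false calls. With the spread of the 5 libraries other than control 3, over 26925 models, the quasi-likelihood test recovered 99% and 29%, with 12 false calls. Simulated libraries were drawn independently, without the likeness of controls 1 and 2. The 200 changed models are also far fewer than the 4605 that the exact test called. The recovered shares are therefore not the power of the tests in these data.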

Results

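Leaf transcripts of Paulownia elongata were compared between 3 libraries from plants kept at 40 °C for 24 hours and 3 libraries from plants kept at 25 °C. The comparison asks which transcripts differ in level after a day of heat. Estimated reads per library were 3570524, 2425787 and 2487845 in heat replicates 1 to 3, and 1337663, 730315 and 2153266 in control replicates 1 to 3. The unit of measurement was the transcript model, a coding sequence known only by its identifier, and 23984 of 43380 models had enough reads to be tested.

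A set of 718 models was 4-fold or more higher in heat in both of 2 comparisons that share no library, and 275 were 4-fold or more lower in both. The first comparison set heat libraries 1 and 3 against control 3, the long-fragment libraries. The second set heat library 2 against controls 1 and 2, the short-fragment libraries. These 2 comparisons follow the division by fragment length and were set up after the data were seen. Of the arrangements below that use every library, this one had the fewest models in opposite directions and the highest correlation. Another 87 models differed 4-fold or more in opposite directions in the 2 comparisons. Lists of these sizes with no relation would share 306 models on the higher side and 77.2 on the lower side. This takes every model as equally likely to enter a list, so a larger shared count is not by itself a sign of agreement. With heat 1 in the place of heat 2 the counts were 771 higher, 226 lower and 283 opposite, and with heat 3 they were 696, 194 and 337. Unrelated lists would then share 336 higher and 112 lower with heat 1, and 357 and 123 with heat 3. At a 16-fold difference with heat 2, 46 models were higher in both, 7 were lower in both and 0 went in opposite directions. Across the 23984 models, which are not independent replicates, the log2 differences of the 2 comparisons correlated at r = 0.45, and at 0.34 and 0.25 with heat 1 or heat 3 in the place of heat 2. No test stands behind these counts, and with a prior count of 5 in place of 1 the 718 and 275 became 265 and 108. Without control 3, with heat 1 and 3 set against control 1 and heat 2 against control 2, they were 4278 and 1753, and with controls 1 and 2 exchanged they were 4266 and 2064. Each of these comparisons rests on control 1 or control 2. Both lie apart from all other libraries, control 3 included, so the larger counts cannot be put down to heat alone. The same limit holds for the second comparison behind the 718 and 275, which used controls 1 and 2. It had 6318 models 4-fold or more higher and 2702 lower. The first comparison, with control 3 as its only control, had 1162 and 685.

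The 718 higher models took 4.01%, 4.25% and 4.99% of the reads in the 3 heat libraries. The same models took 0.216%, 0.558% and 0.525% in controls 1 to 3. The 275 lower models took 0.354%, 0.326% and 0.245% of reads in heat, and 2.07%, 2.03% and 2.79% in the controls. These shares describe sets chosen on the same libraries. The median coding length was 600 bases in the higher set and 300.0 bases in the lower set, against 579 bases over all tested models.

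With all 6 libraries, edgeR's quasi-likelihood test called 1 model higher in heat and 0 lower at an adjusted p of 0.05. Without adjustment, 3258 models were higher and 3891 lower at p under 0.05 with TMM scaling, 3733 and 3306 with DESeq2 size factors, and 3462 and 3008 with library totals. Both directions came to 7149 with TMM scaling. Splits that mix the groups also gave such models. Long-fragment against short-fragment libraries gave 3645, heat 1 with controls 1 and 2 against the rest gave 2792, and the other splits gave 25 to 1571. With the real groups, the next smallest adjusted p in the quasi-likelihood test was 0.0755, shared by 798 models. At a threshold of 0.10 that test called 1480 higher and 2040 lower. On the same filtered models edgeR's exact test called 2251 higher and 2354 lower. limma-voom called 0 in either direction, with a smallest adjusted p of 0.0521 and 4487 higher and 3207 lower models at an unadjusted p under 0.05. DESeq2 with its own scaling and filter gave an adjusted p to 30550 models and called 2197 higher and 2169 lower. With the filtered models and TMM scaling it gave one to 23831 models and called 1888 higher and 2630 lower. Leaving out control replicate 3 raised the quasi-likelihood counts to 9267 higher and 5768 lower of 26925 models tested. That fit keeps only controls 1 and 2, which lie apart from all other libraries, so these counts cannot be put down to heat alone. Leaving out any other single library gave 0 calls in the quasi-likelihood test, with 1877 to 2642 models higher and 2388 to 2959 lower at an unadjusted p under 0.05.

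**Figure D1:**
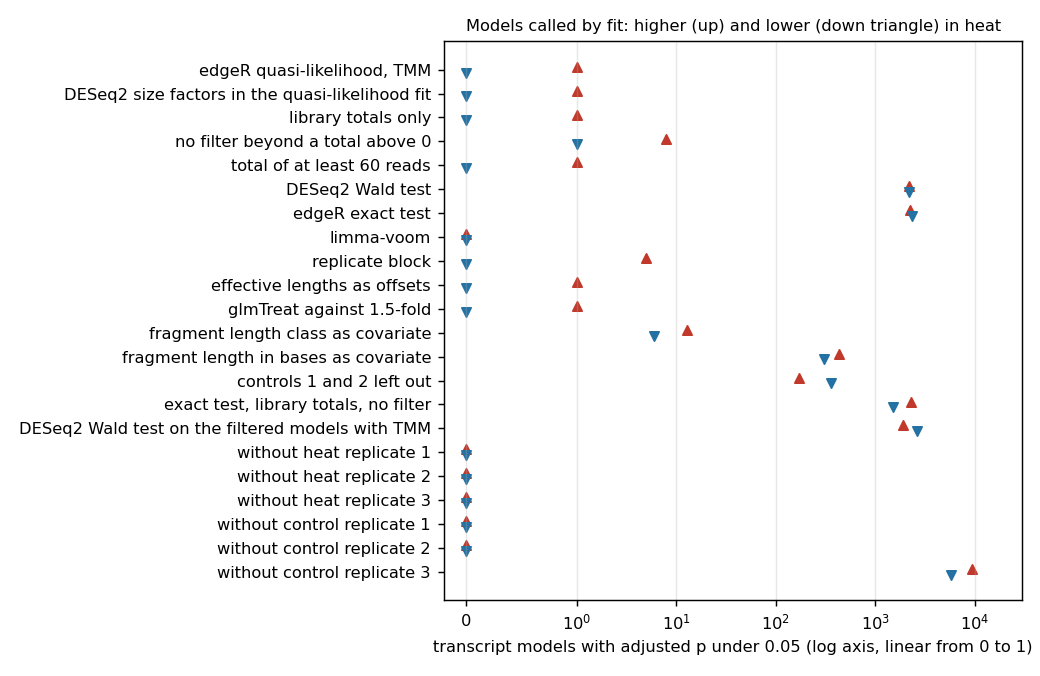
Number of transcript models with an adjusted p under 0.05 (horizontal log axis, linear between 0 and 1) in each fit (vertical axis). Triangles pointing up are models higher in heat and triangles pointing down are models lower in heat. The quasi-likelihood fit of all libraries gave 1 and 0, and the fit without control replicate 3 gave 9267 and 5768.

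The model that passed the threshold was TR70242|c1_g1_i4|m.135076, with a coding length of 771 bases. It rose from 1.56 ± 0.134 CPM in the controls to 107 ± 15.6 CPM in heat (SD, n = 3 per group). The log2 fold change was 6.07 with a standard error of 0.51 and an adjusted p of 0.0323 in edgeR's quasi-likelihood test. The controls held 2, 1 and 3 reads and the heat libraries 333, 366 and 222. Pooled reads gave a ratio of 70.8 with an exact 95% interval of 32.4 to 193 for counting error only. Its adjusted p missed the threshold when any library other than control 3 was left out, reaching 0.266. The log2 difference was 5.70 among the long-fragment libraries and 5.89 among the short-fragment libraries.

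The smallest p-value in the authors' deposited table belonged to TR38143|c0_g1_i1|m.75546, of 831 coding bases, which was chosen after its values were seen. It had 783, 280 and 1269 reads in the heat libraries and 0, 0 and 2 in the controls, or 292 ± 229 CPM in heat against 0.314 ± 0.544 CPM (SD, n = 3 per group). The pooled ratio was 538, with an exact 95% interval of 149 to 4442, and 337 without heat 3. Both control reads came from control 3, and without it an allowance of 3 control reads puts the ratio at 166 or more. In the quasi-likelihood test its adjusted p was 0.0755, and the authors' deposited table gives an FDR of 8.01e-11.

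On the lower side, the authors' deposited table led with TR64724|c0_g1_i1|m.123228, a model of 279 coding bases, and TR29321|c0_g1_i1|m.56813, of 885 coding bases. Both were chosen after their values were seen, and neither passed the quasi-likelihood test, where both had an adjusted p of 0.0755. TR64724 stood at 8.70 ± 1.82 CPM in heat and 566 ± 316 CPM in the controls (SD, n = 3 per group). Its fitted log2 fold change was -6.02 with a standard error of 0.68, and -5.32 without control 3. TR29321 had 0, 0 and 1 reads in the heat libraries and 43, 10 and 46 in the controls. Pooled reads put its control level at 215 times the heat level, with an exact 95% interval of 37.7 to 8566. It was 132 times without heat 1 and 141 times without heat 2, and without heat 3, which held the only heat read, an allowance of 3 reads gives 52.0 times or more. The authors' deposited table gives FDR values of 7.98e-09 for TR64724 and 5.08e-06 for TR29321.

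**Figure D2:**
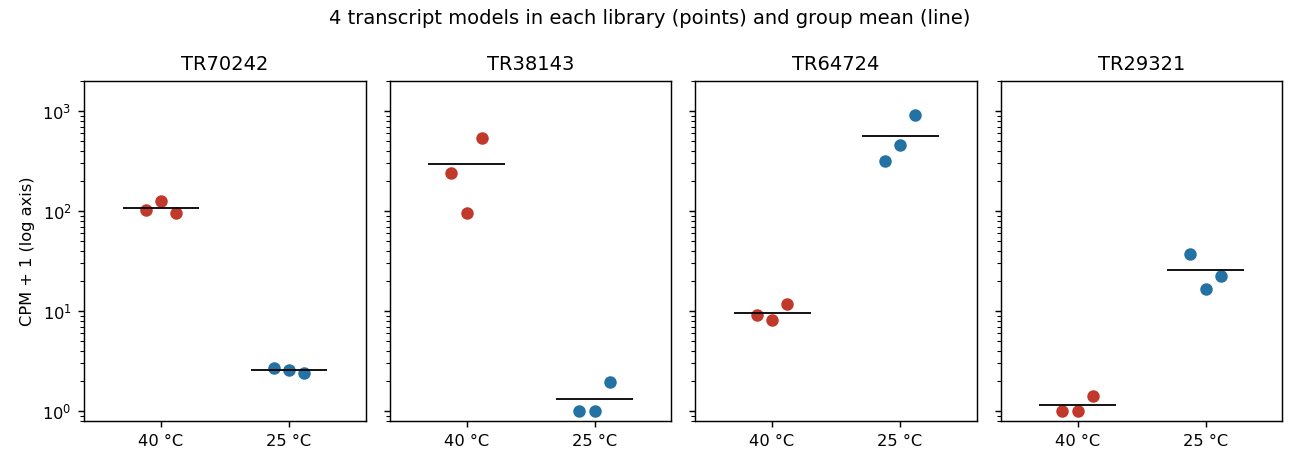
Level of the 4 named transcript models, as CPM plus 1 on a log axis, in the 3 libraries at 40 °C and the 3 at 25 °C. Points are libraries and lines are group means. TR70242 and TR38143 lie higher in every heat library than in any control, and TR64724 and TR29321 lie lower.

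All heat libraries lay above all controls for 5420 tested models and below them for 4001, or 22.6% and 16.7%, where chance gives 5% in each direction. Both directions came to 9421 models, or 39.3%. The split of long-fragment against short-fragment libraries gave 4599, or 19.2%, and the split of heat 1 with controls 1 and 2 against the rest gave 4179, or 17.4%. The gap between the groups was 4-fold or more for 321 models on the higher side and 56 on the lower side. At least 10 reads in every heat library and a listed value of 0 in every control were found for 49 models, with a median of 19, 20 and 19 reads in heat replicates 1 to 3. The reverse pattern was found for 0 models. The reverse criterion was the stricter one, since the shallowest library is a control.

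The authors' deposited table calls 2196 models higher and 1486 lower in heat at an FDR of 0.05, so 59.6% of its calls are higher. With TMM scaling and the expression filter, the exact test gave 48.9% higher. Of the authors' calls, 2593 were among the models tested here and 1089 were not. All of those 2593 had the same direction in the quasi-likelihood fit and an unadjusted p under 0.05, and 2322 had an adjusted p under 0.10. The same libraries underlie both results, so they are not independent.

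The libraries also differed in ways that the temperature groups do not follow. Control replicate 3 correlated with the heat libraries at Spearman's rho of 0.821, 0.775 and 0.809, and with controls 1 and 2 at 0.667 and 0.722, across all models. Controls 1 and 2 correlated with each other at 0.873. The first principal component, with 73.5% of the variance, set controls 1 and 2 apart from the other libraries. The second, with 10.96%, set control 3 apart from the rest.

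**Figure D3:**
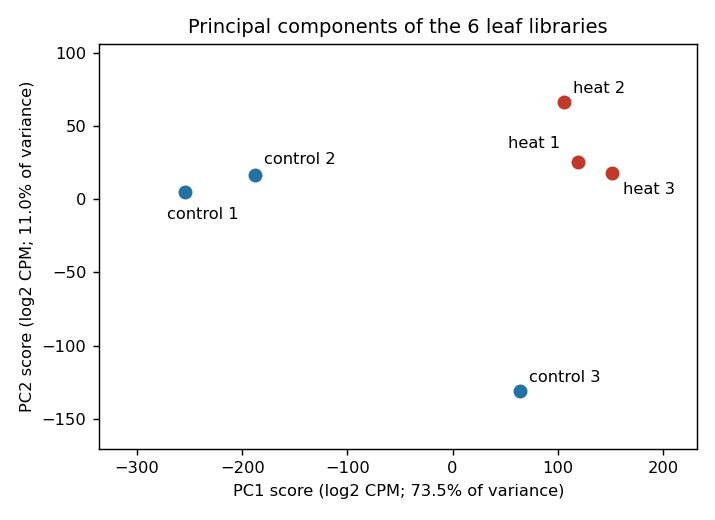
Scores of the 6 libraries on the first and second principal components of log2 CPM, with red points for 40 °C and blue points for 25 °C. Controls 1 and 2 lie at PC1 scores of -255 and -187, and control 3 lies at 64.5, beside the heat libraries at 106 to 152, but at a PC2 score of -131.

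Controls 1 and 2 also listed more transcript models at 0 reads. The number was 14122 and 14448 in these libraries, 3297 in control 3 and 1182, 1650 and 2429 in the heat libraries. Thinned to 730265 reads per library, the mean numbers were 17107 and 14534 in controls 1 and 2, 8455 in control 3, and 7441, 6105 and 7887 in the heat libraries. Fragment length was 132.7 and 140.6 bases in controls 1 and 2 and 140.4 bases in heat replicate 2. It was 165.0 and 158.9 bases in heat replicates 1 and 3 and 165.9 bases in control 3. With the fragment length class as a covariate the quasi-likelihood test called 13 models higher and 6 lower, and with fragment length in bases it called 436 higher and 306 lower.

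A group of abundant transcripts followed fragment length and not temperature. The models of 3 components, TR67422, TR15294 and TR9893, together took 5.41% and 5.46% of reads in heat replicates 1 and 3 and 5.93% in control 3. They took 0.224% in heat replicate 2 and 0.395% and 0.440% in controls 1 and 2. These components were chosen after their values were seen.

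**Figure D4:**
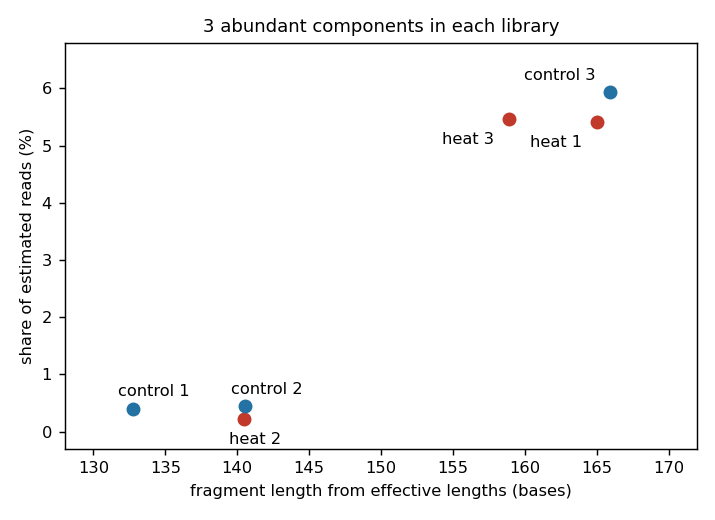
Share of estimated reads taken by the models of the 3 components (vertical axis, percent) against fragment length (horizontal axis, bases) in each library, red for 40 °C and blue for 25 °C. The 3 long-fragment libraries lie between 5.41% and 5.93% and the 3 short-fragment libraries between 0.224% and 0.440%.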

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

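The number of calls depended on the test and on the libraries, while the direction of the named models did not. The named models were chosen for their differences in these same libraries, so a kept direction is no independent support. The 1 call on the higher side and 0 on the lower were also given by DESeq2 size factors, library totals, a minimum total of 60 reads, effective lengths as offsets, the 1.5-fold test and, for the gene of TR70242, isoforms summed to genes. That gene has 1 model, so summing did not change its reads. The quasi-likelihood test gave 8 higher and 1 lower without a filter, limma-voom gave 0 higher, DESeq2 with its own scaling and filter gave 2197 and 2169, and the exact test gave 2251 and 2354. Leave-one-out counts ran from 0 to 9267 on the higher side and from 0 to 5768 on the lower, with the high values from leaving out control replicate 3. The common dispersion was 0.321 with all libraries and 0.135 without control 3. Settings added after the data were seen gave 13 and 6 with fragment length class, 436 and 306 with fragment length in bases, 1480 and 2040 at a threshold of 0.10, 1888 and 2630 with DESeq2 on the filtered models and TMM scaling, and 2264 and 1518 with the exact test on library totals without a filter. Leaving out controls 1 and 2 gave 171 higher and 359 lower, where the lone control is assumed to vary like the heat libraries. The replicate block gave 5 higher and 0 lower. The numbers were not taken to pair the libraries, since no label states a pairing. The correlations of deviations, of which 1 of the 3 same-numbered ones was 0.01, cannot settle it. The counts of 718 and 275 models became 265 and 108 with a prior count of 5 and 1324 higher without a filter. Leaving out 1 library gave 618 to 4278 higher and 229 to 2064 lower, with the high values from leaving out control 3 and all others within 1.5 times. Without heat 2, heat 1 and heat 3 were set against different controls. Without control 3, controls 1 and 2 stood in different comparisons, and both lie apart from all other libraries. The median log2 fold change of all tested models was 0.08 with TMM, 0.23 with library totals and 0.21 with DESeq2 size factors. TR70242 was past the threshold in 15 of 21 alternative fits, TR38143 and TR64724 in 9 and TR29321 in 7, and each kept its direction in all 21. The cause was not tested for the differences between tests. Depth limits the low end, since 3 reads are 4.76 CPM in control 2. The gene list tests and the removal of plastid, mitochondrial and ribosomal transcripts were not run, because the files do not pair identifiers with descriptions.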

Other observations

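Tests of the patterns below were chosen after the results were seen, except the thinning test of depth and the count of splits for the quasi-likelihood test.

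The sets that differed 4-fold or more in both comparisons came from many genes. The 718 higher models belonged to 704 genes by their identifiers and the 275 lower models to 271, with 0 genes in both sets. Of the genes in the higher set, 78 had 2 or more tested models, and all of these models were in the set for 7 of them. In the lower set it was 4 of 80 genes. Reads shared between isoforms are divided by Salmon's estimate, so a difference confined to 1 isoform is uncertain. By their identifiers, some models of a gene share an isoform number and differ only in model number. Division of reads between isoforms does not by itself account for a difference between such models. They were not counted apart from models of different isoforms, and why models of the same gene differed was not tested. In the authors' deposited table, 668 of the 718 models are called higher and 243 of the 275 lower. These models were chosen for large differences in the libraries that the authors tested, so the overlap is not independent support. Of 4605 exact test calls, 4553 were called in the same direction by the quasi-likelihood test without control 3. That fit uses the same libraries except control 3, and it called 9267 higher and 5768 lower of 26925 models.

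Control 3 was also set against the models called without it. Those models were chosen for a gap between heat and controls 1 and 2. Such a choice by itself tends to leave any other control nearer to heat than these 2 are. The values below are therefore no unbiased view of control 3. The 1534 models also passed a filter that used control 3. Of all 9267 such models higher in heat, control 3 was nearer to controls 1 and 2 than to heat for 1867, or 20.1%. Of all 5768 lower in heat it was nearer to them for 1120, or 19.4%. Over the 1534 models that passed the filter on all 6 libraries and were 16-fold or more higher in heat than in controls 1 and 2, the level in control 3 lay a median of 0.75 of the way to heat on the log2 scale.

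Control 3 correlated better with the heat libraries than with the other controls, and 3 technical explanations were tested. Lower depth of controls 1 and 2 is argued against by thinning: at 1 depth, rho with heat exceeded rho with the other controls by 0.0787 on average (SD 0.00157 over 20 thinnings), against 0.108 with all reads. A heat library with the wrong label is argued against by 80 models that were 16-fold or more below every heat library in control 3, where the heat libraries had 0, 30 and 15 against each other. Heat RNA mixed into control 3 would need a share near 33.2%, and only a share of this size was tested. It is the median ratio of control 3 to heat over 49 models unread in controls 1 and 2 and past a minimum of 20 CPM. They are another set than the 49 models listed at 0 in every control. Yet 31 of the 9739 models with enough heat reads to show such a share lay at 0.1 or less of the expected level. That level is what the share gives from the lowest heat library. Only 2 of these 31 were among the 49 that set the share. The same count for heat libraries 1 to 3 against the other heat libraries was 0 of 10546, 10 of 10685 and 4 of 10497. A first form of that test left it open, with a 5th percentile of the ratio at 0.102 of its median and a bound of 0.1. A difference between the plants or the preparation of controls 1 and 2 and all others may remain, and the labels give nothing to test it.

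The 3 components that took 5.41% to 5.93% of the reads of the long-fragment libraries kept nearly fixed proportions. The ratio of TR15294 or TR9893 to TR67422 varied at most 1.04-fold over the 6 libraries, while each component's share varied at least 26.4-fold. This is consistent with 1 RNA source present in differing amounts, and without sequence its identity stays open. A length preference of long-fragment libraries is argued against by 1333 models within 10% of the longest model's 1569 coding bases, whose median log2 difference was 0.49 against 4.05 for that model. Over these 1333 models the SD was 1.20 and the interquartile range 1.65. Their median lay just under the bound set for it after the data were seen. Fragment length and the amount of this source separate the libraries in the same way, so a shared preparation batch cannot be excluded.

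Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split was 1 of the 10 by the quasi-likelihood test, with 1 call against a highest other of 0. By the exact test it was also 1 of 10, with 4605 calls against a highest other of 798. That highest other split was the one between long-fragment and short-fragment libraries.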
